A study of Mus musculus with 10 samples.

How the data were processed

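The series holds 10 single mouse embryos (C57BL6/J) collected at the late 2-cell stage, 5 injected at the 1-cell stage with mRNA encoding Duxbl and 5 with mRNA encoding the red fluorescent protein mCherry. Per the labels the mRNA was at 200 ng per µl; per the series' design text it was injected 24 h after hCG, the hormone that triggers ovulation, and embryos were taken 48 h after hCG. Per the labels' protocols, strand-specific libraries were made from single embryos with a SMART-Seq kit and read as 61 bp pairs. Each library is 1 embryo, so the p-values for single genes and library properties measure the spread between embryos. Groups and replicate numbers were taken from the sample titles, where the Duxbl group is written with a digit 1 in place of the letter l; the design text spells the gene Duxbl.

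The submitters' processing notes list Trimmomatic 0.39, STAR 2.7.10a, Picard 2.25.5, featureCounts 2.0.2, DESeq2 1.30.1 and the mouse build mm39, with no role or order given. The annotation release, the strand setting of the counting and the scaling method are not given in the sources used here. The deposited values are treated as a score with no fixed range: whole numbers that behave as read counts divided by 1 factor per library and rounded by the authors. This was read from the values, because low whole numbers are skipped or pile up at regular spacing in a way that raw counts would not show. A factor per library was fitted on values under 150 over a grid of step 0.0001. Between 99.9% and 100% of those values could arise from whole counts divided by it. With a factor above 1 no whole number is skipped, so this share is 100% by construction and tests only factors below 1. The fitted factors ran from 0.789 to 1.37. Multiplying each library's total by its factor gave an implied depth of 748511 to 1591515 reads per embryo. The exact reads behind rounded values were not rebuilt, so no count model was used. A floor of 3 reads corresponds to a value of 2.18 to 3.80 depending on the embryo, and such floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

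The planned test was a count model, fixed before the data were examined along with the gene lists, the rule for named genes and most of the other settings tried. Since the values are not counts, the test was changed to limma 3.58.1 (R 4.3.3) on log2(value + 2), with a variance trend and robust moderation. Genes with a value of at least 10 in at least 5 embryos were tested, which kept 9545 of the 30477 genes of the table. Fold changes are on the log2(value + 2) scale, Duxbl minus mCherry, and understate the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. Gene lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Library properties and sums over gene families were compared by a two-sided exact permutation test over all 252 assignments, whose smallest p is 0.00794, with 37 properties and 10 families adjusted as separate groups. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

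The lists covered transient 2-cell transcripts, Eif1a-like copies, Obox genes, regulators of genome activation, maternal transcripts, maternal mRNA clearance, ribosomal proteins, nucleolar factors, the spliceosome, the proteasome, general RNA polymerase II factors, pluripotency and early lineage genes, trophectoderm, replication-dependent histones, chromatin, p53 targets, interferon response, stress, cell cycle, mitochondrially encoded genes, oxidative phosphorylation, Pramel genes and Y-linked genes. The p53 list also holds Trp53, the gene for p53 itself. Markers of cumulus cells, oviduct, sperm and blood were fixed as well. The table used here holds 0 genes of chromosome M, so the mitochondrially encoded list has no value. Named genes are every Duxbl gene, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM and groups that do not overlap, leaving out predicted and clone-type symbols. From each list the up to 4 called members with the smallest adjusted p were taken, or the most abundant member where none was called, and the most abundant uncalled 2-cell transcript. The rule gave 98 genes.

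The test was checked on simulated values for this comparison, 5 simulations over 9545 genes with 200 genes changed in each. It recovered 27.2% of 2-fold and 90% of 4-fold changes, and 2.64% of its calls were unchanged genes. Simulated genes were drawn independently and no embryo departed from its group, so these shares do not cover error from movement shared by many genes. Each simulation also changed 200 genes, against 3895 called in the data. The adjusted p threshold loosens as more genes change, so the recovered shares do not measure recovery in the real comparison. Gene length and GC content came from a GRCm38 annotation by gene ID, which held 29747 of the 30477 IDs; coordinates are those of the deposited table. Other settings tried were further scalings, filters, pseudocounts, fold threshold, replicate block, array weights, moderation, length and GC correction, set tests and leaving out each embryo.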

Results

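The transcriptomes of 10 single late 2-cell mouse embryos were compared, 5 injected with Duxbl mRNA and 5 with mCherry mRNA. Duxbl is a double homeobox gene related to Dux, an activator of transient 2-cell transcripts. The question, as the series title gives it, concerns Duxbl in the suppression of zygotic genome activation, the onset of transcription from the embryo's own genome. Implied depth ran from 748511 to 1591515 reads per embryo. The Duxbl mean exceeded the mCherry mean by 12608 reads, with an SD of 312259 in Duxbl and 318684 in mCherry embryos (n = 5 each, exact permutation p = 0.944). Between 17093 and 20819 genes had a value of at least 1 in an embryo. The 50 most abundant genes took 12.9% ± 1.14 of the total in Duxbl and 9.13% ± 1.12 in mCherry embryos (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.042 over 37 properties, no overlap).

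The injected gene was measured first. Duxbl1 (ENSMUSG00000048502, mm39 chromosome 14, 25979001 to 25990512, plus strand, protein coding) had a normalized read count of 3720 ± 1608 in Duxbl and 235 ± 97.6 in mCherry embryos (SD, n = 5). Its log2 fold change was 3.96 with a standard error of 0.36 (adjusted p = 0.000176). The lowest Duxbl embryo, at 1854, lay above the highest mCherry embryo, at 338. Reads from injected mRNA and from the embryo's own gene were not separated, and this was the 1 Duxbl gene in the table.

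**Figure D1:**
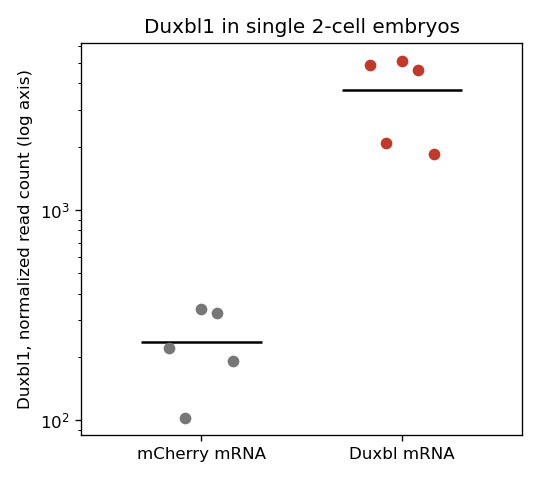
Normalized read count of Duxbl1 (log axis) in each of 5 mCherry and 5 Duxbl embryos, with horizontal lines at the group means. The Duxbl embryos sit between 1854 and 5123 and the mCherry embryos between 103 and 338.

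Duxbl embryos had lower transcripts of transient 2-cell genes, of regulators of genome activation and of the machinery for making ribosomes and proteins, while a set of maternal transcripts was higher. Each of these lists was called by camera with a preset correlation and none with an estimated one (adjusted p = 0.344 with an estimated correlation for the lowest of them). Across the 10 lists called with the preset of 0.01, the estimated correlation ran from 0.177 (general RNA polymerase II) to 0.689 (nucleolar factors). It was 0.652 for ribosomal proteins. The camera p-values at the preset are too small if genes of a list move together to that extent. The control embryo mCherry replicate 2 shared the changes, for some genes only in part. Of 9545 genes tested, 3895 were called, 1555 higher and 2340 lower in Duxbl embryos (limma, adjusted p under 0.05). By more than 1 on the log2 scale, 985 were higher and 2056 lower. The groups did not overlap for 1370 genes, 609 higher and 761 lower, where chance gives 0.794% of genes or 75.8. The split depended on scaling: 39.9% of calls were higher with the authors' values, against 53.7% with upper-quartile scaling, which moved the median of all genes from -0.04 to 0.18. With length and GC trends removed 51.2% were higher.

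The largest falls were in Ubtfl1 (log2 fold change -5.40, standard error 0.77, adjusted p = 0.0012), from 257 ± 142 in mCherry to 7.60 ± 11.5 in Duxbl embryos (SD, n = 5). Alppl2, a placental-type alkaline phosphatase, had a log2 fold change of -5.36, Exoc3l2 of -5.25, Usp17lb of -4.88 and the homeobox gene Obox8 of -4.64. Eid2, Spic, Arg1, Tor1b and Crxos completed the 10 largest falls, at -4.41 to -4.15. After Duxbl1 the largest rises were in Stc2 (log2 fold change 3.37, standard error 0.43, adjusted p = 0.000797), a secreted glycoprotein, from 2.80 ± 2.17 to 47.6 ± 26.6 (SD, n = 5). Cers4, a ceramide synthase, had a log2 fold change of 3.18, Samd11 of 3.07, the metalloproteinase inhibitor Timp3 of 2.96 and Duox2 of 2.95. Ahrr (2.91), Grhl3 (2.83), the long noncoding RNA Rian (2.73) and Mbp completed the 10 largest rises. Several of these had means near 3 reads in mCherry embryos, so their folds are imprecise. Among the mCherry embryos, replicate 2 was highest for Cers4 (23), Timp3 (4), Duox2 (30), Ahrr (3), Grhl3 (14), Rian (25) and Mbp (12). It was not highest for Duxbl1, Stc2 or Samd11.

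Among transient 2-cell transcripts, 14 of 21 tested were lower, 0 higher and 7 not called, with 16 lower adjusted over the list alone. The median log2 fold change was -1.91 (camera adjusted p = 3.21e-06; adjusted p = 0.344 with an estimated correlation). The control mCherry replicate 2 lay at -1.07 from the mCherry mean on this list, inside the Duxbl range of -3.73 to -0.83, with the other mCherry embryos at -0.07 to 0.58. Besides Ubtfl1 and Usp17lb, Zscan5b had a log2 fold change of -3.07 and Tdpoz4 of -3.28. Zfp352, the most abundant member not called, had 43.6 ± 47.2 in Duxbl and 95.6 ± 45.7 in mCherry embryos (SD, n = 5, limma adjusted p = 0.0635). It passed without Duxbl replicate 2 (0.0215), Duxbl replicate 4 (0.0255) or mCherry replicate 2 (0.0348). Summed over copies that can share reads, Zscan4 genes were at 11.6 ± 16.3 in Duxbl and 70.8 ± 17.2 in mCherry embryos (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0198 over 10 families). The Eif1a-like copies, none of which passed the filter, summed to 6 ± 5.79 against 98 ± 51.4 (SD, n = 5, exact permutation p = 0.0159, adjusted p = 0.0198). In such sums mCherry replicate 2 lay above every Duxbl embryo for Zscan4 (50, Duxbl 0 to 39), Tdpoz (98, Duxbl 1 to 75) and Usp17l genes (142, Duxbl 0 to 86). It lay inside the Duxbl range for Tcstv genes (17, Duxbl 5 to 22) and the Eif1a-like copies (12, Duxbl 0 to 13). Duxf3, the Dux gene itself, was at or under the floor in most embryos, with 2.60 ± 3.29 against 0.20 ± 0.45 (SD, n = 5, exact permutation p = 0.167, adjusted p = 0.185).

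Of 14 tested regulators of genome activation, 12 fell, 1 rose and 1 was not called, with the same counts adjusted over the list alone (median -1.29; camera adjusted p = 0.000235; adjusted p = 0.344 with an estimated correlation). On this list mCherry replicate 2 lay at -0.85, next to the highest Duxbl embryo at -0.94, with the other mCherry embryos at 0.03 to 0.32. Nr5a2, an orphan nuclear receptor, went from 255 ± 99.6 to 35.2 ± 6.83 (SD, n = 5, log2 fold change -2.68, limma adjusted p = 0.000776). Dppa2 had a log2 fold change of -2.95, Dppa4 of -2.20 and Gabpa of -1.92. Of these, mCherry replicate 2 lay above every Duxbl embryo for Nr5a2 (94, Duxbl 29 to 44) and Dppa2 (86, Duxbl 9 to 44). It lay inside the Duxbl range for Gabpa (135, Duxbl 74 to 138) and Dppa4 (78, Duxbl 22 to 82). Of the 7 genes on the Obox list, from a homeobox family of the early embryo, Obox8, Obox6 (-4.02) and Obox3 (-4.20) fell and Obox1 rose by 1.04. Summed over copies that can share reads, 9 Obox3 copies were at 21.6 ± 27.4 against 337 ± 180. The 16 Obox4 copies, not on the list, summed to 8.60 ± 7.37 against 53.8 ± 28.0 (SD, n = 5, exact permutation p = 0.0159, adjusted p = 0.0198 for each). These sums were 44 and 17 in mCherry replicate 2. The Obox list was not called by camera (adjusted p = 0.601) and was called by fry, which does not compare it with other genes (adjusted p = 0.0295). Its median of 0.07 and mean of -1.43 differed in sign, and adjusted over the list alone 3 were higher and 3 lower. On the Obox list mCherry replicate 2 lay at -0.60, with the other mCherry embryos at 0.05 to 0.24 and the highest Duxbl embryo at -0.71. The Obox1 call was lost without Duxbl replicate 1, 3 or 5, or mCherry replicate 1, 3 or 4, at adjusted p of 0.0559 to 0.078. It was also lost with the replicate number as a block (limma adjusted p = 0.0549).

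Of 78 ribosomal protein genes tested, 72 fell, 0 rose and 6 were not called, with 73 lower adjusted over the list alone. The median log2 fold change was -2.11 (camera adjusted p = 7.28e-20; adjusted p = 0.344 with an estimated correlation), and -1.43 with length and GC trends removed. Rpl7 had a log2 fold change of -3.40 and Rps27 of -3.19, and Rps7 went from 120 ± 32.2 to 26.8 ± 12.3 (SD, n = 5). Their processed pseudogenes can share reads. Of 38 nucleolar factors, which make and modify ribosomal RNA, 37 fell and 1 was not called, with 38 lower adjusted over the list alone (median -1.96; camera adjusted p = 1.34e-12; adjusted p = 0.344 with an estimated correlation). Nop56 was at -2.21, Nhp2 at -3.46 and Polr1a, the largest subunit of RNA polymerase I, at -2.60. One control embryo, mCherry replicate 2, moved with these groups. On the ribosomal protein list it lay at -1.10 from the mCherry mean, with the other mCherry embryos at 0.12 to 0.35 and the Duxbl embryos at -2.50 to -0.94. On the nucleolar list it lay at -1.27, below the highest Duxbl embryo at -1.11.

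**Figure D2:**
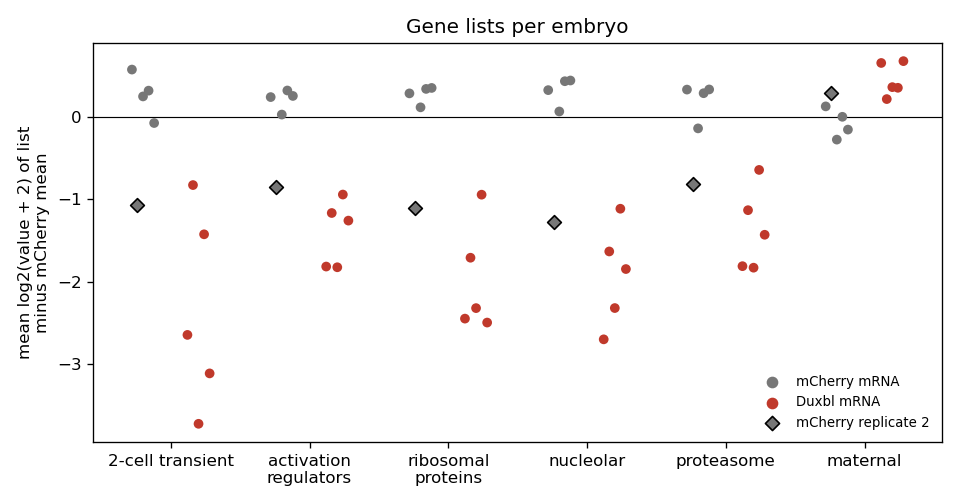
Mean of log2(value + 2) over the tested genes of 6 lists, minus the mCherry mean, with 1 point per embryo (5 mCherry in grey, 5 Duxbl in red). The diamond marks mCherry replicate 2, which lies at -1.10 for ribosomal proteins and -1.07 for transient 2-cell transcripts.

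Lists of other general machinery were lower too, by camera with a preset correlation. In the proteasome 20 of 29 fell and 9 were not called, with 22 lower adjusted over the list alone (median -1.52; camera adjusted p = 1.49e-06; adjusted p = 0.344 with an estimated correlation), among them Psmb4 (-1.99) and Psmd12 (-2.12). In the spliceosome 21 of 33 fell and 12 were not called, with 22 lower adjusted over the list alone (median -1.26; camera adjusted p = 5.63e-06; adjusted p = 0.35 with an estimated correlation), among them Snrpa (-2.31) and Srsf1 (-1.93); 15 fell without mCherry replicate 5. The control mCherry replicate 2 lay inside the Duxbl range on the proteasome (-0.82, range -1.83 to -0.64) and spliceosome (-0.78, range -1.69 to -0.59) lists, and at -0.61 on the stress list (range -1.26 to -0.17). On the general RNA polymerase II list it lay at -0.50, and the highest Duxbl embryo at -0.68. On the oxidative phosphorylation list it lay at -0.16, inside the other mCherry embryos (-0.23 to 0.17) and outside the Duxbl range of -1.29 to -0.27. Of 29 general RNA polymerase II factors 18 fell, 1 rose and 10 were not called, with 19 lower and 1 higher adjusted over the list alone (median -1.05; camera adjusted p = 0.000281; adjusted p = 0.344 with an estimated correlation), among them Polr2e (-2.41) and Gtf2f2 (-2.92). Without mCherry replicate 1, 11 of these fell. In oxidative phosphorylation 23 of 41 fell and 18 were not called, with 24 lower adjusted over the list alone (median -0.95; camera adjusted p = 7.57e-05; adjusted p = 0.344 with an estimated correlation), among them Ndufs8 (-2.76) and Atp5b (-1.38). Without Duxbl replicate 1 or 5 or mCherry replicate 5, 14 of that list fell, and 15 without mCherry replicate 4; with upper-quartile scaling 15 fell and with length and GC trends removed 11. The list was not called with a minimum value of 50 (adjusted p = 0.297). The stress list, with 7 of 16 lower over all genes and adjusted over the list alone, had a camera adjusted p of 0.0326 (adjusted p = 0.53 with an estimated correlation). Its call was lost without Duxbl replicate 1 (0.0509) or 5 (0.0561), or mCherry replicate 1 (0.069) or 3 (0.0505), with a minimum of 5 CPM in 5 embryos (0.0528) and with length and GC trends removed (0.164). Its members Hsp90ab1 and Hsp90aa1, cytosolic chaperones, fell, with log2 fold changes of -2.36 and -1.41.

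Maternal transcripts, which the oocyte stores, were higher as a list relative to other genes. A change in total mRNA per embryo cannot be seen, so this need not be a rise in their amount. Of 36 tested, 11 rose, 2 fell and 23 were not called, with the same counts adjusted over the list alone (median 0.53; camera adjusted p = 0.000271; adjusted p = 0.344 with an estimated correlation). The number that rose depended on single embryos: 18 without mCherry replicate 2, 7 without Duxbl replicate 1 or 3, 6 without Duxbl replicate 5 or mCherry replicate 4 or 5, and 5 without mCherry replicate 3. It was 4 of 40 with no filter on low values, 4 of 36 with a log2 threshold of 1, 20 with upper-quartile scaling, 17 with array weights and 27 with length and GC trends removed, and mCherry replicate 2 lay at 0.30 on this list, within the Duxbl range of 0.22 to 0.68. Bmp15, an oocyte growth factor, went from 378 ± 315 to 1055 ± 375 (SD, n = 5, log2 fold change 1.72, limma adjusted p = 0.00533). Tcl1 had a log2 fold change of 2.19, a call lost with no filter on low values (adjusted p = 0.0552), and Cnot6l, a deadenylase subunit, of 1.24. Dppa3, also on the maternal list, fell by 1.56 on the log2 scale. Of 11 genes for maternal mRNA clearance 5 rose and 2 fell, with the same counts adjusted over the list alone, and the list was not called by camera (adjusted p = 0.0857) and was called by fry (adjusted p = 0.0105). Without mCherry replicate 3, or with no filter on low values, 3 rose. Of the 11 clearance genes 1 fell without Duxbl replicate 1 or 3 or mCherry replicate 1, 4 or 5, with upper-quartile scaling and with a log2 threshold of 1. Cnot7 had a log2 fold change of 1.35 and the m6A reader Ythdf2 of -1.55.

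The remaining lists were not called by camera. Fry, which asks only whether the genes of a list move on balance one way, called the pluripotency (adjusted p = 0.00731), p53 (0.0067) and cell cycle (0.0299) lists, and not trophectoderm (0.185), chromatin (0.363), histones (0.671) or Pramel (0.631). With no filter on low values camera called p53 (0.0243) and cell cycle (0.00524). Among pluripotency and lineage genes 6 of 14 fell and 2 rose (7 and 2 adjusted over the list alone), with Dppa5a at -2.23, Esrrb at -1.34 and Gata4 at -1.25 (camera adjusted p = 0.187). Among trophectoderm genes 3 of 11 rose and 1 fell (5 and 2 adjusted over the list alone), with Dab2 at 2.08 and Gata3 at 1.82 (camera adjusted p = 0.129). On this list mCherry replicate 2 lay at 1.35, above every Duxbl embryo (0.05 to 1.02), with the other mCherry embryos at -0.65 to 0.11. Without mCherry replicate 2, 6 rose and the list was called by camera (adjusted p = 0.0266), as it was with array weights (0.0312). Of 35 cell cycle genes 16 fell and 3 rose (16 and 4 adjusted over the list alone), with Ccne1 at -1.55 and the oocyte kinase Wee2 at 2.34 (camera adjusted p = 0.189). Of 28 chromatin genes 7 fell and 2 rose over all genes and over the list alone, with the H3K4 demethylase Kdm5b at -2.22 and Dnmt3l at 1.33 (camera adjusted p = 0.837). Of 16 genes on the p53 list 5 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.172). Those that fell include Sesn2 (-2.48) and Trp53 itself (-1.51). The Trp53 call was lost without Duxbl replicate 5 or mCherry replicate 1 or 4, and with length and GC trends removed. Of 42 histone genes 3 fell and 1 rose (1 lower adjusted over the list alone), with H1f5 at -2.06 (camera adjusted p = 0.939). Of 19 Pramel genes 6 rose and 6 fell over all genes and over the list alone, with Pramel7 at -4.24 and Pramel6 at -3.89 (camera adjusted p = 0.666). With no filter on low values 17 of 42 Pramel genes fell and camera called the list lower (0.00118), and with a minimum value of 50, where 5 of 7 rose and 0 fell, it called it higher (0.00723). Among 4 tested interferon genes Ddx58 rose by 1.91 and Stat2 fell. The Stat2 call was lost without Duxbl replicate 1 or 3 or mCherry replicate 3, 4 or 5, at adjusted p of 0.0614 to 0.0727. It was also lost with the replicate number as a block (limma adjusted p = 0.064).

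Small counts in these lists moved with single embryos. The p53 list genes that fell numbered 8 without mCherry replicate 2, 3 without mCherry replicate 5 or Duxbl replicate 1, 3 or 5, and 2 without mCherry replicate 1 or 4. The p53 list gene that rose was lost without Duxbl replicate 1, 3 or 5 or mCherry replicate 3 or 4. The histone genes that fell numbered 6 without Duxbl replicate 4, 5 without mCherry replicate 2 and 1 without Duxbl replicate 3 or 5 or mCherry replicate 3. The histone genes that rose numbered 0 without Duxbl replicate 1, 2 without Duxbl replicate 2 or 5 or mCherry replicate 2 or 4, and 3 without mCherry replicate 5. Without mCherry replicate 2, 4 chromatin, 6 cell cycle and 3 Obox genes rose. Of the pluripotency genes 1 rose without Duxbl replicate 3 or mCherry replicate 1, 3 or 5, and of the trophectoderm genes 2 fell without Duxbl replicate 2 or 4 or mCherry replicate 2. With upper-quartile scaling 6 chromatin, 8 cell cycle, 5 trophectoderm, 4 histone and 3 Obox genes rose. With length and GC trends removed 15 histone, 7 cell cycle, 5 trophectoderm and 4 chromatin genes rose, and 10 cell cycle and 2 p53 genes fell. With array weights 8 histone genes fell, and 7 cell cycle, 6 trophectoderm, 4 chromatin and 3 Obox genes rose. With median-of-ratios or trimmed-mean scaling 4 chromatin and 2 Obox genes rose. Histone genes that rose numbered 2 with median-of-ratios and 3 with trimmed-mean scaling. Without Duxbl replicate 2, 2 Obox genes rose. With a log2 threshold of 1, 0 histone and p53 genes and 1 pluripotency gene rose.

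On average the embryos of a group resembled one another more than those of the other group, with 1 exception. Mean Spearman correlation across tested genes, which are not independent replicates, was 0.849 within mCherry, 0.863 within Duxbl and 0.67 between groups. The exception, mCherry replicate 2, averaged 0.847 to the Duxbl embryos and 0.731 to the other mCherry embryos. On the first principal component of the 500 most variable genes (81.8% of their variance) it lay at 7.67, with the other mCherry embryos at -44.2 to -38.4. The Duxbl embryos were spread as well: replicates 4 (10.5) and 2 (12.7) lay near mCherry replicate 2, and the others at 38.7 to 48.2. Duxbl replicate 4 correlated more with mCherry replicate 2 (0.898) than with any other Duxbl embryo (0.809 to 0.886). Without mCherry replicate 2, 5044 genes were called, 2203 higher and 2841 lower, and 3873 of the calls were shared with those of all embryos.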

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

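All tests of mCherry replicate 2 described here were chosen after the result was seen. An embryo was singled out where its gap to the nearest of the 5 embryos of its group, divided by the range of that group, exceeded 0.71. Among 244 groups of 5 values, for 98 named genes, the lists and library properties on their own scales, 38 passed, or 15.6%, where chance gives about 5%. Of these 38, 32 concerned mCherry replicate 2, 3 Duxbl replicate 4, 2 Duxbl replicate 1 and 1 mCherry replicate 3; the genes are not independent.

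In mCherry replicate 2 the lowest value of its group was found, with this ratio in brackets, for Alppl2 (0.856), Exoc3l2 (0.822), Eid2 (0.791), Spic (0.724), Tor1b (0.762), Crxos (0.841), Zscan5b (0.765), Obox6 (0.717), Obox3 (0.728), Nr5a2 (0.729) and Dppa4 (0.721). The same held for Rps7 (0.837), Rps25 (0.716), Nop56 (0.938), Nhp2 (0.892), Polr1a (0.858), Hnrnpu (0.858), Psmd11 (0.72), Polr2d (0.856), Polr2h (0.78) and Dppa5a (0.736). Kdm5b (0.905), Sesn2 (0.766), Hsp90aa1 (0.904), Atp5b (0.839), Pramel7 (0.81) and Epcam (0.897) were lowest there too. Of the lists, Obox (0.776), genome activation regulators (0.751), ribosomal proteins (0.838) and nucleolar factors (0.781) were lowest in this embryo. Its share of the 50 most abundant genes was the highest of the mCherry group, at 11.1% (0.787). In other embryos, Gtf2f2 (0.812) was lowest and Ddx58 (0.726) highest in Duxbl replicate 1. H4c14 (0.759), Uqcrb (0.844) and the oxidative phosphorylation list (0.849) were highest in Duxbl replicate 4, and Rrm2b (0.839) was lowest in mCherry replicate 3.

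A candidate explanation for mCherry replicate 2 is a Duxbl-injected embryo under the mCherry label, which its Duxbl1 value of 103 argues against, since it is the lowest of all embryos and the lowest Duxbl embryo has 1854. A shallower library is argued against by its implied depth of 914053 reads, inside the range of the other mCherry embryos. Slower development, a damaged embryo, or another handling fault that Duxbl1 cannot show, stays open and was not tested here.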

How the results depend on the processing

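All limma calls that a setting shared with those reported had the same sign. More genes were lower than higher under each setting except upper-quartile scaling (2312 higher, 1993 lower) and removal of length and GC trends (2155 higher, 2056 lower). The number called ran from 2829 to 5044 when single embryos were left out, with 1048 to 2203 higher and 1763 to 2841 lower. It was 4305 with upper-quartile, 4004 with total-value and 4140 with median-of-ratios scaling, and 4452 with no filter on low values. The planned minimum of 5 CPM in 5 embryos proved looser than the filter used and gave 4357. With a log2 threshold of 1, 985 genes were higher. Chosen after seeing the data, a minimum value of 50 gave 1980 calls, 944 higher and 1036 lower, among 4014 genes tested instead of 9545. Also chosen afterwards were trimmed-mean scaling of all genes (4112), pseudocounts of 0.5 (3767) and 8 (3977), array weights (5191), moderation without robustness (3915) and removal of length and GC trends (4211). The transient 2-cell, ribosomal protein and maternal lists kept their calls under each setting that tested them by camera except with an estimated correlation, where each had an adjusted p of 0.344. With the minimum of 50 the transient 2-cell and Obox lists had 4 members each and no set test, and the log2 threshold and moderation without robustness do not enter camera. With copies collapsed to families the transient 2-cell list had 9 of 14 lower and an adjusted p of 9.16e-05. Of 19 lists camera called 10 with the preset and 0 with an estimated correlation, and fry called 15. With the minimum of 50, 3 of 4 transient 2-cell and 30 of 31 ribosomal protein genes fell. The Pramel list was called lower with no filter on low values (adjusted p = 0.00118) and higher with the minimum of 50 (0.00723), and Kdm5d, not called, moved to a log2 fold change of 0.0661 with upper-quartile scaling; the cause was not tested. Of 98 named genes, 49 were tested under all 25 other settings, and 41 of these kept their direction and their side of the threshold. The other 49 had values too low for the minimum of 50, and over the remaining settings 85 of the 98 were unchanged. The labels do not say whether the replicate numbers pair the embryos. Deviations of embryos with the same number had correlations of -0.33 to 0.12. These gave no sign of pairing but cannot exclude it, since large differences between single embryos could hide it. With the number as a replicate block 3287 genes were called, and no embryo correlated best with the embryo of its own number in the other group. The planned count-model tests and voom were not run, since the values are not counts. Depth limits genes with values near 3 reads. In simulations with 200 genes changed, far fewer than were called here, 27.2% of 2-fold changes were recovered.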

Other observations

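The test of length and GC content and the count over other splits were written before their results were seen; the other tests were chosen after. The genes named in the next paragraph, other than those of fixed lists, were chosen after their values were seen.

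Of 218 long noncoding RNA genes 79 were higher and 39 lower in Duxbl embryos, and of 8802 protein coding genes 1430 were higher and 2189 lower. These counts were not tested against each other. Long noncoding RNA took 1.96% ± 0.18 of the total in Duxbl and 1.17% ± 0.18 in mCherry embryos (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.042, no overlap). In mCherry replicate 2, the highest control, it took 1.42%. The protein coding share was 95.5% ± 0.16 against 95.8% ± 0.42 (SD, n = 5, exact permutation p = 0.167, adjusted p = 0.268). Of 63 small nucleolar RNA genes tested by limma 0 were called. The 3 immunoglobulin constant region genes tested were all higher, Ighg2b at 192 ± 52.4 against 77.2 ± 41.6, Ighg3 at 67.8 ± 12.6 against 19.6 ± 17.7 and Ighg1 at 53 ± 17.1 against 23.4 ± 10.7 (SD, n = 5, limma adjusted p = 0.00909, 0.00397 and 0.0168). Blood transcripts were near 0, with Ptprc at 0.20 ± 0.45 in Duxbl and 0 in mCherry embryos and Hba-a2 at 1.20 ± 0.837 against 1 ± 1 (SD, n = 5). Of the cumulus markers 1 passed the filter, Amhr2, lower at 3.80 ± 3.77 against 29.2 ± 14.9 (SD, n = 5). Of 3 oviduct markers tested Epcam was lower at 24.6 ± 21.2 against 191 ± 96.7 (SD, n = 5), with mCherry replicate 2 at 24, and its call was lost with no filter on low values (limma adjusted p = 0.0825). Muc1, at 17 ± 17.4 against 7.60 ± 10.7, and Dnah5, at 12 ± 6.44 against 7.20 ± 4.60, were not called (SD, n = 5, limma adjusted p = 0.165 and 0.338). Odf2, on the sperm list, was higher at 480 ± 106 against 157 ± 109, while Prm2 was at 0.20 ± 0.45 against 1 ± 1.73 (SD, n = 5). The Y-linked transcripts Usp9y, Uty and Zfy2 were at 0 in mCherry replicates 1, 2 and 5 and Duxbl replicates 4 and 5. They were above 0 in the other embryos. Kdm5d, the most abundant on the Y-linked list, had 21 to 33 in the embryos where those were at 0. Its values thus did not follow them, and it was not called (limma adjusted p = 0.72).

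The level of Duxbl1 did not order the Duxbl embryos by ribosomal protein score: replicate 4, at 4651, had the score nearest the controls (-0.94), and replicate 5, at 1854, the farthest (-2.50). With 5 embryos no correlation was computed.

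Lower ribosomal protein transcripts in Duxbl embryos were weighed against technical explanations. For the authors' scaling, the list's median log2 difference was at most -1.88 under 4 other scalings, with upper-quartile scaling. Each scaling shifts all genes of an embryo by 1 factor, and the median of all genes stayed between -0.05 and 0.18. The bound of -0.5 set for the list was out of reach, so this test could not decide. The list fell relative to the median of all genes, and a change in total mRNA per embryo cannot be seen. Length and GC content could account for part: removing both trends moved the list's median from -2.11 to -1.43 and its mean from -1.98 to -1.37 (standard error 0.276 after removal), still below the bound of -0.5. A difference in depth is argued against by group means of implied reads that differ by 12608. The change that mCherry replicate 2 shows without injected Duxbl, of which slower development is 1 untested reading, cannot be told apart. Against that embryo alone the Duxbl mean was at -0.98 but Duxbl replicate 4 was at 0.19, and mCherry replicate 2 is a single library.

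Chance was unlikely to give the number of genes called but was not excluded. The real split was always among the 100 counted, so the share could not fall below 1 in 100. Of 100 splits of the embryos into 5 and 5, drawn from 126, 1 gave at least 3895 calls, the real one. The highest other gave 3819 and exchanged mCherry replicate 2 with Duxbl replicate 4, and the exchange of mCherry replicate 2 with Duxbl replicate 2 gave 3349. The median of the other splits was 0.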
